A study of Trichoderma reesei with 6 samples.

How the data were processed

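RNA of Trichoderma reesei mycelium was sequenced after growth of a strain without cre1 at 28 °C and 200 rpm with 1% cellulose or 2% glucose. There were 6 libraries in 2 groups of 3, and the carbon source in each sample's title gave its group. Libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.8, SAMtools 0.1.18 and DESeq 1.10.1, with no roles or options. The genome build, the gene annotation and the read counter are not given in the sources used here.

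The first deposited table held a normalised signal per gene and library, which is not a whole number of reads. It listed 9129 genes by protein identifier. In each library the deposited values were whole multiples of a fixed step, between 0.605 and 2.76, which is the value of one read. Dividing by this step gave whole reads for 100% of the values, within 0.01 read. The steps matched DESeq-type median-of-ratios size factors computed over the 6 mutant libraries, with a ratio of 1 for each library, a match found from the values. Read totals ranged from 9009170 to 24655534, so that glucose library 1 had the least depth. The second table held the authors' own comparisons of the mutant with the parental strain QM9414, as log2 fold changes, per the file headers. It also held adjusted p-values for each carbon source, per the file headers. Fold changes of 100 and -100 in the deposited table were placeholders and none was called; 25 and 206 genes had them on cellulose, and 67 and 138 on glucose. Of the 206 genes at -100 on cellulose, 131 had no read in any cellulose library and 75 had reads in cellulose library 3 alone, while all 138 at -100 on glucose had no read in any glucose library. The deposited files also held 6 columns of per-library values for the parental strain, which have no sample labels here and were not used in any step.

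Protein identifiers were matched to the locus tags of the reference annotation of strain QM6a, assembly v2.0. Of the 9129 genes, 9072 matched and 226 had a symbol. The authors' build is not named, so the reference served only for gene names and for which genes are neighbours.

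The test of cellulose against glucose was limma 3.58.1 with an intensity trend, in R 4.3.3, on log2(normalised count + 1). Fold changes on this scale understate the change of genes with few reads. Genes with a mean under 10 over the 6 libraries were left out, which removed 953 genes and kept 8176. P-values were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact test of 3 against 3 values cannot reach this threshold, and the model's p-values rest on the spread estimated across genes. The design, the alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 10 largest rises and the 10 largest falls among genes with a symbol that passed the test, and cre1. For cellulose against glucose it also asked for a mean of at least 50 and no overlap between the groups. It added up to 4 members of each gene list with the smallest p. It did not foresee the placeholders, which were left out of the ranking, and the deposited table gives no mean level. In all, 81 genes were named by it for cellulose against glucose, and the values of some of them are not reported here.

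Gene lists by identifier had been written before the data were examined, and a member was kept only where the reference gave its identifier a symbol. This held for 29 of 72 identifiers and left 6 lists, namely cellulose degradation, hemicellulose degradation, cellulase regulators, pentose catabolism, hydrophobins and reference genes. A list of sugar transporters had no member left. Lists planned by words in gene descriptions could not be made, because the reference gives symbols and no descriptions. In their place 16 lists by symbol were written after the symbols had been seen and before any test of them. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 22 lists, and again with an estimated correlation, with limma's directional fry test and with other designs. For the deposited comparisons, Fisher's exact tests (two-sided) of list counts were added after the counts had been seen. Their background was first all genes of the table, and after a look at the result was limited to the 8788 genes on cellulose and 8789 on glucose that had a fold change other than 0 or a placeholder; adjustment was over 88 tests.

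The scripts were tested on simulated data with the means, library sizes and groups of cellulose against glucose, over 8132 genes of which 200 were changed. The test recovered 24% of the genes changed 2-fold, 76% of those changed 4-fold, 98% of those changed 8-fold and 96% of those changed 16-fold, with 5 false calls among 152. Changes of 2-fold were thus often missed in this simulation. It changed a far smaller share of the genes than the 2403 of 8176 called in the data. The adjusted threshold is stricter where fewer genes change, so these shares do not give the recovery of the real comparison.

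The alternatives were pseudocounts of 0.5 and 10, no filter and a mean of at least 50, quantile normalisation, TMM and median-of-ratios rescaling, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, a fold threshold, no intensity trend, a block for the library number, and leaving out each library in turn. Library weights were added after the data were seen. For the deposited comparisons a stricter adjusted p of 0.01 and a log2 fold change of at least 1 were tried.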

Results

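The data measured transcript levels in mycelium of a Trichoderma reesei strain that lacks cre1 (Δcre1). The gene encodes a zinc-finger repressor of carbon catabolite repression, by which glucose keeps genes for the use of other carbon sources low. Cultures were grown in Mandels-Andreotti medium with 1% cellulose or 2% glucose, and each carbon source had 3 libraries, which the series describes as biological replicates. The recovered read totals were 18370939, 22395248 and 21193732 for cellulose libraries 1, 2 and 3, and 9009170, 23655558 and 24655534 for glucose libraries 1, 2 and 3. The labels do not tell at which culture time (24, 48 or 72 h on cellulose, 24 or 48 h on glucose) a library was taken. One gene without a symbol took 33.3%, 3.53% and 5.42% of the reads of cellulose libraries 1, 2 and 3, and 35.1%, 14.5% and 18.2% of those of glucose libraries 1, 2 and 3. Cellulose library 3 stood apart from its group, with a mean correlation across genes of 0.926 with the other cellulose libraries and 0.850 with the glucose libraries, against 0.788 and 0.797 with the glucose libraries for cellulose libraries 1 and 2.

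The deleted gene was looked at first, because it checks the labels. The cre1 gene had normalised read counts of 2081, 3394 and 3314 in cellulose libraries 1, 2 and 3, and of 997, 525 and 557 in glucose libraries 1, 2 and 3, so no library was at 0. In the authors' deposited table, cre1 was lower in Δcre1 than in the parental strain QM9414 on both carbon sources, with a log2 fold change of -1.96 on cellulose (deposited adjusted p = 9.74e-11) and -3.11 on glucose (deposited adjusted p = 2.83e-17). By the fold changes of the authors' deposited table, the level in the mutant was 25.8% of the parental level on cellulose and 11.6% on glucose. Which part of the gene was deleted is not given in the sources used here, and read positions were not analysed here.

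The first comparison asked how transcript levels of the mutant differed between cellulose and glucose. The groups also differed in the concentration of the carbon source and may differ in culture time. An effect of the carbon source itself cannot be told apart from these. Most genes of cellulose degradation were far higher on cellulose. The normalised read count of cel7a, which encodes the main cellobiohydrolase, was 185869 ± 177664 on cellulose and 744 ± 815 on glucose (SD, n = 3 each), a log2 fold change of 8.09 (SE 0.88, limma adjusted p = 0.000853). The endoglucanase genes of the list rose as well, with log2 fold changes of 8.46 (SE 0.96) for cel5a, 6.72 (limma adjusted p = 0.00439) for cel12a and 4.64 (SE 0.62) for cel7b, and so did cel61a at 7.61 (SE 0.62) and cel61b at 7.62 (SE 0.98), which encode lytic polysaccharide monooxygenases. With a pseudocount of 10 the cel61b log2 fold change was 6.80 and the cel12a log2 fold change 6.02. The gene cel5b, outside the list and named after its values were seen, had counts of 601, 916 and 4427 in cellulose libraries 1, 2 and 3 and 3452 ± 223 on glucose (SD, n = 3), a log2 fold change of -1.36 that did not pass (limma adjusted p = 0.154). Of the 13 tested members of the cellulose degradation list, 10 rose, 1 fell and 2 did not pass the test, and 11 rose and 1 fell when adjusted over the list alone.

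Within that list the β-glucosidase genes, whose products split cellobiose, did not move together. The gene cel3a rose by a log2 fold change of 6.35 (SE 0.77) and cel1b by 1.56 (SE 0.42). The count of cel3b fell from 49975 ± 7945 on glucose to 22014 ± 9860 on cellulose (SD, n = 3 each), a log2 fold change of -1.28 (limma adjusted p = 0.0383). The gene cel1a, at 1.35 (SE 0.43), narrowly missed the threshold (limma adjusted p = 0.0513), and its groups did not overlap. The gene cel3c, at 0.81 (SE 0.44), did not pass (limma adjusted p = 0.199). The call of cel3b was lost without cellulose library 1 or any glucose library and in edgeR's test, with adjusted p-values from 0.0502 to 0.118 over the settings that lost it. The spread within the cellulose group was wide for the list, with cel7a counts of 389224, 107631 and 60751 in cellulose libraries 1, 2 and 3.

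**Figure D1:**
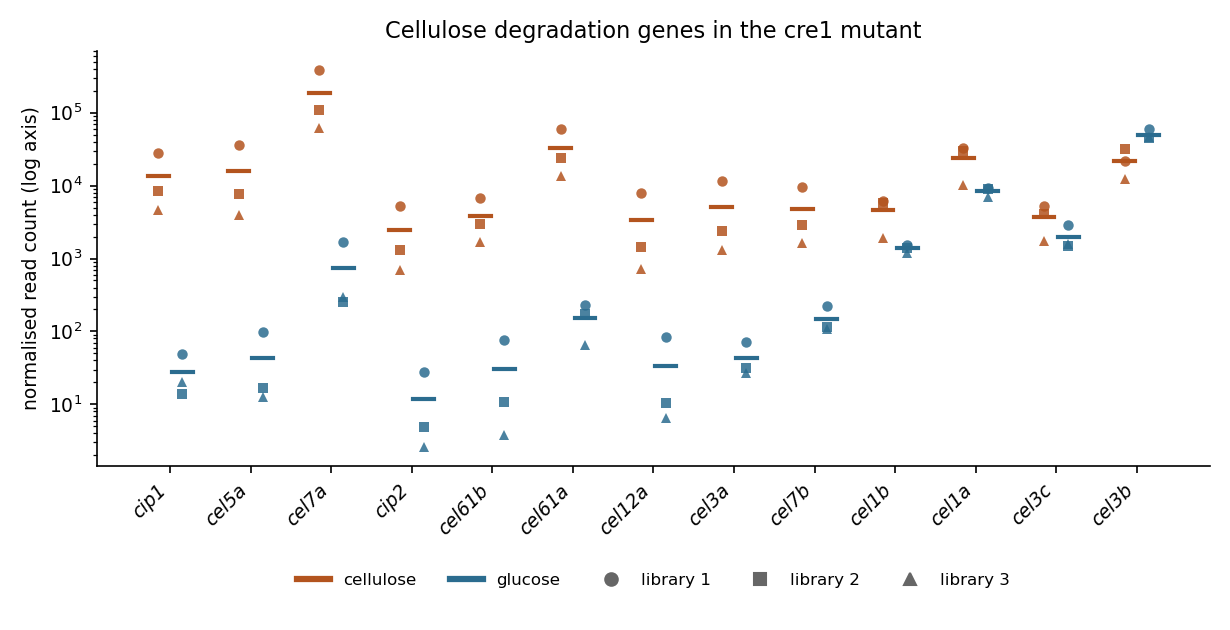
Normalised read counts (log axis) of the 13 tested genes of cellulose degradation in Δcre1, ordered by their fold change. Points are single libraries, with a shape for each library number, horizontal bars are group means, and colours give the carbon source. The cellulose points of cel7a lie between 60751 and 389224 and its glucose points between 254 and 1685, whereas cel3b is lower on cellulose.

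The hemicellulose list kept 2 members with a symbol, and both rose, axe1 (an acetyl xylan esterase) by a log2 fold change of 9.91 (SE 0.75) and man5a (a mannanase) by 8.62 (SE 0.86). Most members written for this list, such as xyn1, xyn2 and bxl1, had no symbol and were left out of it. On glucose axe1 had 4 reads and man5a 22 in the 3 libraries together, and with a pseudocount of 10 the axe1 log2 fold change was 7.61 and the man5a log2 fold change 7.47. The gene axe2, outside the list and named after its values were seen, went the other way without passing (log2 fold change -0.76, limma adjusted p = 0.0502). Limma's camera test with a preset correlation placed the cellulose degradation list (adjusted p = 1.65e-05) and the hemicellulose list (adjusted p = 0.0217) above the other genes. Neither call held when the correlation was estimated from the 6 libraries (adjusted p = 0.469 with an estimated correlation for both).

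Among the regulators of cellulase genes, 2 of 6 tested members rose, both over all genes and adjusted over the list alone. Among them was the remaining cre1 signal, with a log2 fold change of 2.11 (SE 0.30, limma adjusted p = 0.00255). The main activator gene xyr1 had 11995 ± 8051 normalised counts on cellulose and 5336 ± 486 on glucose (SD, n = 3 each) and did not pass (log2 fold change 0.95, limma adjusted p = 0.148). The values of ace1, hap2 and hap3 were 0.23, 0.28 and 0.17, and none passed. Camera did not call the list (adjusted p = 0.0715). The result for xyr1 depended on cellulose library 3 and on the test. Without that library the log2 fold change was 1.43 (limma adjusted p = 0.00964). With all libraries DESeq2 called xyr1 (adjusted p = 0.0253). So did limma with library weights (adjusted p = 0.0428), which were chosen after the data were seen.

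Genes of 2 hydrophobins, which are small secreted surface proteins, also rose. The gene hfb2 was at 109518 ± 51207 normalised counts on cellulose and 6826 ± 5626 on glucose (SD, n = 3 each), a log2 fold change of 4.30 (SE 0.66), and hfb3 rose by 3.75 (SE 0.61). The third member, hfb1, had counts of 21.2, 47.2 and 1263 in cellulose libraries 1, 2 and 3 and did not pass (limma adjusted p = 0.128). Thus 2 of 3 members rose, with the same number adjusted over the list alone, and camera did not call the list (adjusted p = 0.0652). Of the pentose catabolism list, 1 of 2 members rose, also adjusted over the list alone: xyl1, a xylose reductase gene, with 1793 ± 720 normalised counts on cellulose and 803 ± 203 on glucose (SD, n = 3 each, limma adjusted p = 0.0396), while xdh1 was at a log2 fold change of 0.36. The call of xyl1 was lost under quantile normalisation, without an intensity trend, and without any one library other than cellulose library 3. Where lost, its limma adjusted p was at least 0.0513, with 0.0974 and 0.106 without cellulose library 1 and 2. Camera did not call the list (adjusted p = 0.339). The identifier written for lad1 in this list had no symbol and was left out. The gene that the reference names lad1 has another identifier and was named after its values were seen. It rose by a log2 fold change of 1.76 (SE 0.26, limma adjusted p = 0.00279), so the list does not stand for the whole pathway.

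Chitin degradation was a list chosen after the gene symbols of the reference had been seen, but before its members were tested. Its members were taken by symbol alone, and whether the product of each acts on chitin was not checked. Of its 16 tested members, 9 rose, 1 fell and 6 did not pass, and 9 rose and 1 fell when adjusted over the list alone. The normalised count of chi18-rel1 was 4744 ± 1434 on cellulose and 90.7 ± 49.3 on glucose (SD, n = 3 each), a log2 fold change of 5.78. The chitinase gene chi18-6 rose by 1.88 (SE 0.29), chi18-15 by 6.21 (SE 0.82) and chi18-12 by 5.60 (SE 0.90). On glucose chi18-15 had 6 reads and chi18-12 had 17 in the 3 libraries together, and with a pseudocount of 10 the chi18-15 log2 fold change was 3.82 and the chi18-12 log2 fold change 3.71. The member that fell, named after its values were seen, was chi18-4 at -0.91 (SE 0.27), and leaving out any library other than cellulose library 3 lost its call. Camera placed the list above the other genes (adjusted p = 0.00633), but not with the correlation estimated (adjusted p = 0.469 with an estimated correlation).

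Ribosomal protein genes, a list chosen in the same way, included many that fell on cellulose. Of 42 tested members, 25 fell, 0 rose and 17 did not pass, and 32 fell when adjusted over the list alone, while 0 rose at an unadjusted p under 0.05 in limma and 0 in edgeR or DESeq2. The list's median log2 fold change was -0.64. The count of rla0, an acidic ribosomal protein gene, fell from 14394 ± 2058 on glucose to 6565 ± 828 on cellulose (SD, n = 3 each), a log2 fold change of -1.13 (limma adjusted p = 0.00536), and rpl30 and rpl28 fell by 1.05 and 1.03 on the log2 scale. Camera placed the list below the other genes (adjusted p = 1.65e-10; adjusted p = 0.469 with an estimated correlation). Without cellulose library 2, glucose library 2 or glucose library 3, the number of members that fell was 13, 9 and 9, and under quantile normalisation it was 38.

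**Figure D2:**
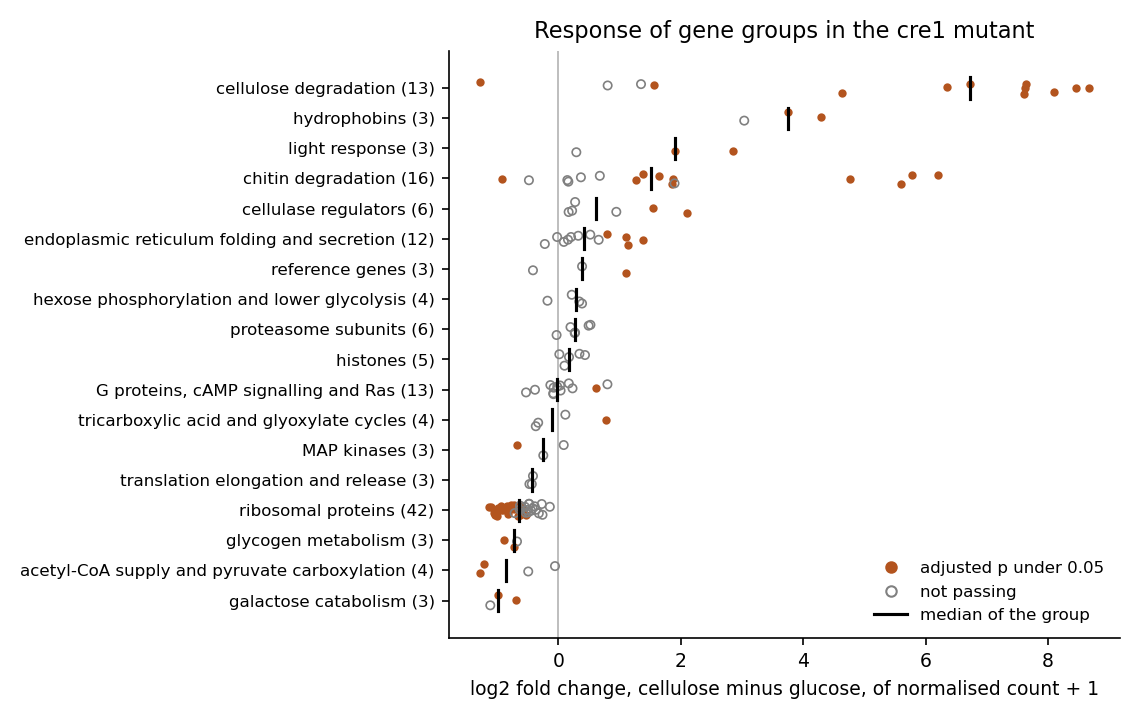
Log2 fold change, cellulose minus glucose, on the scale of normalised count + 1, for members of the gene lists with at least 3 tested members in Δcre1. Filled points passed limma's adjusted p of 0.05, open points did not, and black bars are medians; the median is 6.72 for cellulose degradation and -0.64 for ribosomal proteins. Under quantile normalisation the medians of the reference genes, the proteasome, the histones and the glycolysis list change sign.

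Of the other named genes, ooc1 rose by a log2 fold change of 8.98 (SE 0.76), and the largest falls outside the lists above were those of acl1, acl2 and fdh1. The genes acl1 and acl2, for the subunits of ATP citrate lyase, which makes cytosolic acetyl-CoA, fell by 1.22 (SE 0.27) and 1.28 (SE 0.31) on the log2 scale. The formate dehydrogenase gene fdh1 fell by 1.24 (SE 0.25). The call of acl1 was lost without cellulose library 2, glucose library 1 or glucose library 2, and that of acl2 without cellulose library 1, cellulose library 2 or glucose library 2 (adjusted p from 0.0503 to 0.0569 and from 0.0627 to 0.0696). Among the genes often used as references for expression, 1 of 3 rose, also adjusted over the list alone. It was sar1, a GTPase gene of vesicle transport, at 1.11 (SE 0.15), while gpd1 was at 0.39 and tef1a at -0.41 without passing, tef1a passing as lower under quantile normalisation (adjusted p = 0.0142), and camera did not call the list (adjusted p = 0.465).

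Over the 8176 genes tested, 1490 were higher and 913 lower on cellulose by limma with Benjamini-Hochberg adjustment, and 1159 and 486 of these by at least 1 on the log2 scale. The values of the 2 groups did not overlap for 48.7% of the genes, where chance gives 10%. Under quantile normalisation 1279 genes were higher and 1520 lower, so that 45.7% of the calls were higher against 62.0% as deposited, and the median log2 fold change of all genes moved from -0.02 to -0.18. The lower count was 576 without cellulose library 2, and 525, 361 and 456 without glucose library 1, 2 and 3, and the higher count was 996 without glucose library 2.

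The second comparison asked how the mutant differed from the parental strain, for which only the authors' own fold changes were used. The parental libraries belong to another series, and whether they were grown and sequenced together with the mutant is not given. A difference between batches therefore cannot be told apart from an effect of the loss of cre1. On glucose, where the repressor acts in the parent, the authors' deposited table gave cel1a and cel1b, for intracellular β-glucosidases, at log2 fold changes of 6.01 (deposited adjusted p = 1.07e-56) and 3.28 (deposited adjusted p = 9.36e-18) in the mutant over the parent. In the same comparison of the authors' deposited table, xyr1 was higher by 5.19 (deposited adjusted p = 4.57e-43), cel3b by 5.12, the hexose transporter gene hxt1 by 4.06 and cel3c by 2.84. The main cellobiohydrolase gene cel7a was not called on glucose in the authors' deposited table (log2 fold change 1.45, deposited adjusted p = 0.878). The 5 named genes called lower on glucose in the authors' deposited table were hfb1 at -9.97, cre1 at -3.11, cro1 at -1.72, snf1 at -1.26 and chi18-7 at -1.16. Of 13 members of the cellulose degradation list, 4 were higher on glucose and 0 lower in the authors' deposited table. This was an excess of higher calls by Fisher's exact test (two-sided, adjusted p = 0.0302 over 88 tests). The 4 were the β-glucosidase genes cel1a, cel1b, cel3b and cel3c. No cellobiohydrolase, endoglucanase or lytic polysaccharide monooxygenase gene of the list was called, nor was cel3a. This does not show that they were unchanged, since cel12a, with 57 reads on glucose in the mutant, was at 3.17 without a call.

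On cellulose other genes led the comparison. In the authors' deposited table, nag2, which encodes an N-acetylglucosaminidase, was higher by 2.12, ooc1 by 1.93 and the chitinase gene chi18-2 by 1.60. The largest falls among named genes called lower on cellulose in the authors' deposited table were cel61b at -2.10 (deposited adjusted p = 2.5e-16), cre1 at -1.96, cel12a at -1.14 (deposited adjusted p = 0.0291) and fdh1 at -1.08. For cel7a the authors' deposited table gave 0.36 on cellulose (deposited adjusted p = 0.962), and xyr1 was at 0.62 without a call (deposited adjusted p = 0.632). Of the cellulose degradation list, 1 of 13 members was higher and 2 were lower on cellulose in the authors' deposited table. The median log2 fold change of the list was 0.35 there. Among the members without a call, cel61a was at 2.08 (deposited adjusted p = 0.142), opposite to cel61b.

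Many ribosomal protein genes were higher in the mutant on each carbon source. Of 42 members, 21 were higher and 0 lower on cellulose in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 1.17e-12), and 31 were higher and 0 lower on glucose (Fisher's exact test, two-sided, adjusted p = 1.19e-31). Their median log2 fold changes in the authors' deposited table were 0.67 and 0.98. For the proteasome list, 5 of 6 members were higher on cellulose in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.000231), among them psa5 at 0.87 and psa7 at 0.86, and 0 on glucose. Histone genes were higher on glucose for 4 of 5 members of the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.000422) and on cellulose for 2 of 5 (adjusted p = 0.342). Of genes in the authors' deposited table, 3 of 4 for hexose phosphorylation and lower glycolysis, such as pgk1 at 1.01 and eno1 at 0.94, were higher on cellulose (Fisher's exact test, two-sided, adjusted p = 0.0205) and 0 on glucose. These Fisher tests were added after the counts had been seen, and all lists of this paragraph were chosen after the symbols. The tests treat genes as independent, which they are not. Their background also held genes with few reads, which are harder to call. On cellulose chi18-12, with 535 reads in the mutant, was at 1.09 without a call in the authors' deposited table. There rpl44, with 14962 reads, was called at 1.08. Lists of genes with many reads can show an excess for this reason, which was not tested.

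Counted over all genes of the authors' deposited table, 594 were higher and 221 lower in the mutant on cellulose, and 394 were higher and 303 lower on glucose, at a deposited adjusted p under 0.05. On both carbon sources 84 genes of the authors' deposited table were higher, where independent lists of these sizes would share 25.6, and 20 were lower, where they would share 7.34. Opposite calls in the authors' deposited table were found for 23 genes that were higher on cellulose and lower on glucose (19.7 for independent lists), snf1 with 0.89 and -1.26 among them, and for 17 the other way (9.54 for independent lists), hxt1 with -0.87 and 4.06 and fdh1 with -1.08 and 2.06 among them. The numbers for independent lists were computed over all 9129 genes. These include the placeholders, none of which was called, so the numbers are lower than over genes that could be called. Whether an effect differed between the carbon sources was not tested. All 85 genes with reads in cellulose library 3 but in neither of the other cellulose libraries carried a placeholder or a fold of 0 on cellulose in the authors' deposited table.

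**Figure D3:**
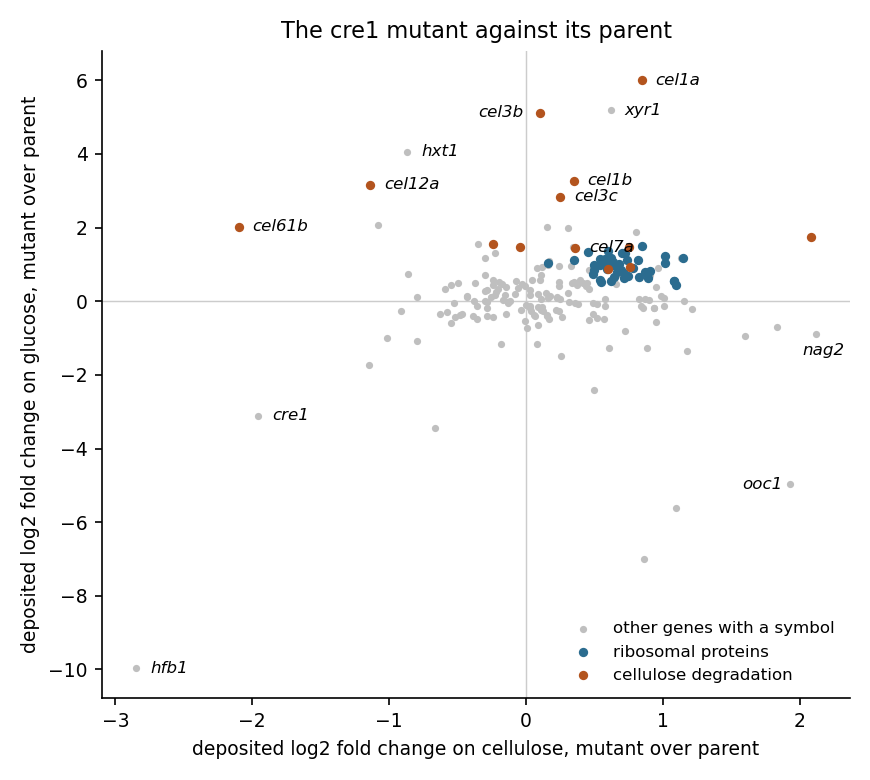
Log2 fold changes of Δcre1 over the parental strain in the authors' deposited table, on cellulose (x axis) and on glucose (y axis), for 222 genes with a symbol. Each point is one gene, with cellulose degradation and ribosomal protein genes coloured; 4 genes with a placeholder are left out. The genes cel1a, xyr1 and cel3b lie at 6.01, 5.19 and 5.12 on the y axis, whereas cel61b lies at -2.10 on the x axis.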

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

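The tests on placeholders and on cre1 and the swap test were chosen after the results were seen. The mixture test was set before its result was seen, but after the correlations between libraries.

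The deposited comparison on cellulose stood out for data it seems to leave out. In all, 85 genes had reads in cellulose library 3 and in neither of the other cellulose libraries, with up to 1066 reads and a median of 2, and the authors' deposited table lists 75 of them with the placeholder of -100 and 10 with a fold of 0 on cellulose. These are the marks it gives to the 231 genes without any read in the 3 cellulose libraries. A filter on low counts as the source is argued against, because 0% of the 126 genes with reads in cellulose library 1 alone or 2 alone carried such a mark. That the deposited comparison on cellulose was made without cellulose library 3 would need all such genes to be marked, and 100% of them were; this is a hypothesis from the table alone, and no biological explanation was tested. On glucose, 0% of the genes with reads in a single library were marked.

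Cellulose library 3 also lay closer to the glucose libraries than the other cellulose libraries did. For 104 genes high in cellulose libraries 1 and 2 and low on glucose, its median level was 44.1% of theirs. The quartiles were 30.6% and 56.6%. These genes were chosen by their level in libraries 1 and 2, which favours a lower level in library 3. A second measure treated each cellulose library alike, as its position on the way from the glucose mean to its group mates. The medians were 110%, 104% and 73.2% for cellulose libraries 1, 2 and 3. A mixture with RNA from the glucose cultures of Δcre1 would add about the same share of each glucose-specific transcript. The shares of 31 such genes had quartiles of 1.39% and 72.1%, a ratio of 51.8. The limit set for a mixture was a ratio under 2, so a mixture with this RNA alone does not account for the pattern. RNA from other cultures was not tested. A swap with a glucose library is argued against by a mean correlation that is higher by 0.0756 with its own group. A difference in culture time between libraries stays open, since the labels do not give it and it was not tested.

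Reads at cre1 in each library of its deletion strain were the other pattern. A parental library among the 6 would stand above its group by about the parental fold, which is 8.63 on glucose and 3.88 on cellulose in the authors' deposited table. On glucose the highest library was 1.90 times the lowest, which argues against one such library there. On cellulose it was 1.63 times the lowest, or 2.80 times by CPM, its share of the library total, which is nearer to the parental fold, but the second library was close to the highest, which was 1.02 times it, or 1.08 times by CPM, so that no single library stood out. Reads from parts of the locus outside the deletion cannot be told apart from reads of another origin, since the 11.6% of the parental level left on glucose in the authors' deposited table says nothing of read positions.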

How the results depend on the processing

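Library weights, which gave 1328 lower genes, and the lists by symbol were chosen after the data were seen. The higher count of cellulose against glucose stayed within 1.5 times 1490 in every setting run, from 996 without glucose library 2 to 1724 with library weights, while the lower count of 913 was 1520 under quantile normalisation, 486 with a log2 fold change of at least 1, and from 361 (without glucose library 2) to 1365 (without cellulose library 3) with a library left out; the cause was not tested. Rescaling by median-of-ratios factors moved nothing, since the deposited values already have them, and edgeR and DESeq2 called 1520 and 1702 genes higher and 805 and 1082 lower, 53 genes having no adjusted p in DESeq2. Of the 1538 values of 81 named genes under the alternatives, 1443 kept their direction and side of the threshold, 66 lost a call, 29 gained one and 0 reversed; the losses fell on 15 genes, none beyond the log2 fold change of -1.28 of acl2 in size, among them acl1, acl2, acu9, bip1, cdc42, cel3b, gal1, gal10, gys1, rpl36, rpl8, snc1, tmk2 and xyl1. Of 22 lists, 4 passed camera with the preset correlation, 0 with an estimated one (1 at an unadjusted p under 0.05, chitin degradation) and 13 passed fry, which asks only whether a list's genes move one way. With a replicate block, 1264 genes were higher and 647 lower. The calls of acu9, cdc42, cel3b, gal1 and tmk2 were lost, and the same number of lists, 4, passed. The deviations of same-numbered libraries correlated at 0.115, -0.142 and -0.0316, and 2 of 6 libraries correlated best with their own number. With 3 libraries per group this cannot show whether the numbers pair the libraries. The gene with the most reads took its largest share in the libraries numbered 1, at 33.3% on cellulose and 35.1% on glucose. In the authors' deposited table, an adjusted p under 0.01 left 105 genes lower on cellulose, 260 higher and 169 lower on glucose, 42 higher on both, 10 lower on both and 16 in opposite directions. A log2 fold change of at least 1 left 318 higher and 106 lower on cellulose, 40 higher on both, 10 lower on both and 21 in opposite directions, both by the construction of a stricter threshold. A limit on the mean level of the deposited comparisons was not run, since the table gives none. Depth was lowest in glucose library 1, with 9009170 reads, and how it limits genes of different levels was not tested.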

Other observations

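Apart from the neighbour test and the splits, whose tests were set before their results were seen, the descriptions below use lists by symbol that were chosen after the symbols were seen.

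Some genes of protein folding and secretion and of light response were higher on cellulose in Δcre1. Of 12 members of the endoplasmic reticulum and secretion list, 4 rose and 0 fell (6 rose adjusted over the list alone), among them the chaperone gene bip1 with a log2 fold change of 1.14 (SE 0.31), pdi1 with 1.38 (SE 0.27) and snc1 with 0.80 (SE 0.19). Camera did not call the list (adjusted p = 0.0652), under quantile normalisation 3 rose and 1 fell, and bip1 lost its call there (adjusted p = 0.209) and without any one library other than cellulose library 3. Without cellulose library 2 or glucose library 1, 2 members of the list rose. Of 3 light-response genes, 2 rose: phr1, a photolyase gene, by 2.85 (SE 0.37) and env1, which encodes a light regulator, by 1.90 (SE 0.38), while blr1 was at 0.30 (camera adjusted p = 0.0682).

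Some sugar storage and galactose genes were lower on cellulose. In the galactose list 2 of 3 members fell (3 adjusted over the list alone), gal10 by 0.99 and gal1 by 0.69 on the log2 scale (camera adjusted p = 0.0682), with none called without glucose library 2 and 1 without cellulose library 1, glucose library 1 or glucose library 3. In the glycogen list gys1 and ugp1 fell by 0.89 and 0.71, 2 of 3 members (3 adjusted over the list alone; camera adjusted p = 0.0652), with 1 called without any one glucose library. In the authors' deposited table gys1 was higher in the mutant on glucose, with a log2 fold change of 1.98 (deposited adjusted p = 7.15e-08). The list of acetyl-CoA supply had 2 of 4 members lower (camera adjusted p = 0.0858), and 4 of 4 under quantile normalisation. Further, 1 of 4 genes of the tricarboxylic acid and glyoxylate cycles rose, acu9 by 0.78 (camera adjusted p = 0.898), 1 of 13 genes of G protein, cAMP and Ras signalling rose, cdc42 by 0.61 (camera adjusted p = 0.898), and 1 of 3 MAP kinase genes fell, tmk2 by 0.68 on the log2 scale (camera adjusted p = 0.395). Under quantile normalisation 0 rose and 1 fell in the list of acu9 and in that of cdc42. The calls of acu9, cdc42 and tmk2 were each lost in at least 6 settings, with adjusted p-values up to 0.122, 0.0985 and 0.0995.

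For 6 lists limma called 0 members. At an unadjusted p under 0.05 these had 1 higher member of 6 for the proteasome, 1 lower of 2 for ATP synthase and 1 lower of 3 for translation elongation and release, and 0 for histones, for hexose phosphorylation and lower glycolysis and for pentose phosphate oxidation. DESeq2 called 1 member lower for ATP synthase and 0 for the other lists, and edgeR called 0. Under quantile normalisation 2 of 2 members of the ATP synthase list and 3 of 3 of the translation list were lower. Without cellulose library 3 both pentose phosphate genes were lower, zwf1 with a log2 fold change of -1.28 (limma adjusted p = 0.00119) and pgd1 with -1.45 (limma adjusted p = 0.00203), and so was atp1 (limma adjusted p = 0.0364). Library weights, chosen after the data were seen, called psb4 of the proteasome higher and zwf1 and erf1 lower. Camera adjusted p-values of the 6 lists lay between 0.285 for translation and 0.659 for glycolysis.

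Genes next to each other on the genome may respond together to the carbon source, a hypothesis set against random gene orders. The log2 fold changes of 7470 neighbouring pairs correlated at 0.278 across pairs, which are not independent replicates, against a highest value of 0.0361 in 1000 random orders. For the 3805 pairs at least 1000 bp apart in the reference the value was 0.263, against a highest of 0.0531, so reads shared by overlapping genes do not account for all of it. Both genes were higher on cellulose in 422 pairs, against a mean of 250 and a highest value of 301 in the random orders. Other sources of a shared response, such as a shared promoter or tandem copies of a gene, were not tested.

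The number of genes called on cellulose against glucose was set beside other splits of the 6 libraries into 3 and 3. The real split called 2403 genes with limma, and the highest of the other splits 0, with 409 genes at an unadjusted p under 0.05 against 3498 for the real one. Of the 10 splits, 1 called as many genes as the real one, which is the real one itself, and 10 splits are too few for a share under 0.05.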
